A study of Danio rerio with 20 samples.

How the data were processed

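Ribosomal-RNA-depleted total RNA libraries were made from pools of 15 whole zebrafish larvae, per the labels. The authors deposited 1 table for the whole series, with a gene name, a length and 20 columns of whole-number counts per gene. Per the submitters' processing notes, fastp, STAR, SAMtools and Subread were used with the GRCz11 assembly; the versions, the parameters and the strand setting are not given in the sources used here. The table's header does not state the unit of the length column.

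Groups were taken from the sample titles, which give genotype, age and a replicate number. In 10 of the 20 samples a second genotype characteristic contradicts the title and the first one, because it follows age and not genotype; the titles match the stated design of 5 samples per genotype and age. The names of the count columns were then compared with the titles, descriptions and characteristics of all samples, and 0 of 20 matched. Assigning columns to groups by their order would be a guess, and assigning them by the level of the targeted gene or of age markers would define the groups by the outcome, so the 20 count columns were not used in any step. Depth per sample, the similarity of replicates and a check of the genotype labels by the targeted gene are consequently not reported.

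Only the gene names and listed lengths were read, with Python 3.11.15. Gene lists for the pathway of Pmm2, for stress responses and for larval tissues, 36 lists with 1085 gene names in all, had been written before the data were examined. Each name was looked up by its symbol, then by an older symbol in the list, then by a single matching synonym in the RefSeq gene table, which was used for names only because its assembly differs from GRCz11. A match was found for 1050 of the 1085 listed names, in 1045 different rows, because 5 rows were each reached by a pair of listed names (try, ela2l, lamp1, pde6h and ciarta); counts of genes with a row are therefore given as different rows. The 13 protein-coding genes of the mitochondrial genome were not found under the symbols listed for them. In the table, 1 row name occurs more than once. The statistical tests and processing alternatives planned before the data were examined were not run.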

Results

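The study measured RNA from whole zebrafish larvae by ribosomal-RNA-depleted total RNA sequencing. Its 20 samples form 4 groups of 5, according to the sample titles: wild-type larvae and larvae with a loss of function of Pmm2, each collected at 5 and at 8 days post-fertilization (dpf). Each sample pooled 15 larvae of 1 genotype. Pmm2 is the phosphomannomutase that converts mannose-6-phosphate to mannose-1-phosphate, the precursor of GDP-mannose. The design implies a comparison of mutant with wild type at each age, a comparison of the ages within each genotype, and a test of whether the genotype effect differs between ages. The series title names the expression of the N-glycosylation machinery and O-GlcNAcylation, the addition of single N-acetylglucosamine residues to nuclear and cytoplasmic proteins, as its subject.

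None of these comparisons was made. The count table has 20 columns of per-sample values, and their names are numbers with an aligner's file ending. The numbers run from 1 to 5, from 11 to 20 and from 26 to 30, so they could be read as 4 blocks of 5, the size of the 4 groups, but nothing in the labels says which block would be which group. Of these names, 0 match a title, a description or a characteristic of any sample. Genotype and age could therefore be given to a column only from its place in the table or from its values, and neither was used. No expression value, fold change, sequencing depth or test is given for any gene, and nothing is stated about whether transcripts of the pathway rose or fell in mutant larvae.

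Which genes the table lists can be stated from its gene rows alone. A row does not show that any read was counted for its gene. The targeted gene, pmm2, has 1 row, with a listed length of 1146. The gene dpagt1, whose product transfers N-acetylglucosamine-phosphate to dolichol phosphate and so starts assembly of the lipid-linked oligosaccharide, has a row with a listed length of 2167. Both subunits of cis-prenyltransferase, an enzyme of dolichol synthesis, have rows, nus1 with a listed length of 1265 and dhdds with 1199. The O-GlcNAc transferase genes ogt.1 and ogt.2 have separate rows, with listed lengths of 5763 and 6577, and the O-GlcNAcase gene appears under its older symbol mgea5 with 5078. The gene mpi, whose product makes mannose-6-phosphate from fructose-6-phosphate, has a row with a listed length of 1503, while no row was matched to pmm1, the paralog of pmm2.

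Nearly all names in the glycosylation lists had a match, as did 1050 of the 1085 listed names over all lists. A high share was therefore not particular to this pathway. The list for genes of the mitochondrial genome was an exception, with a match for 0 of its 13 names. All 19 genes listed for assembly of the lipid-linked oligosaccharide, all 5 for dolichol synthesis and recycling, all 12 oligosaccharyltransferase subunits and all 11 genes of the hexosamine pathway and O-GlcNAc cycling had a row. For GDP-mannose and GDP-fucose supply, 10 of 11 had one, and for N-glycan trimming and branching 32 of 33, man1c1 being the gene without a match. For GPI anchor synthesis and protein O-mannosylation, 35 of 37 had one, with pigy and pigg unmatched. The ER chaperone and unfolded protein response list had rows for 33 of 35 genes, and the ATF4 and amino acid response list for all 32. Among the tissue lists, rows were found for 32 of 33 cartilage genes, all 41 hepatocyte genes, 37 of 38 fast muscle genes and all 43 neuronal genes. Of the 29 exocrine pancreas names, 28 had a match, in 26 different rows, and sycn.1 had none. The 47 photoreceptor names all had a match, in 46 different rows. The names prss1 and try led to the same row, as did ctrc and ela2l in the pancreas list and pde6ha and pde6h in the photoreceptor list. These numbers describe which listed names were found among the row names. A gene without a match may have a row under another symbol. The numbers carry no information on expression.

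Rows were classed by their names only. Of the 47048 rows, 9651 had names starting with trna and were taken as nuclear transfer RNA genes, with a median listed length of 73. Another 22, with short names starting with trn, were taken as transfer RNA genes of the mitochondrial genome. A further 8750 rows carried a locus identifier in place of a symbol, 5305 a clone-type name, and the remaining 23320 another symbol, with a median listed length of 2240.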

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

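The planned tests of genotype, age and their interaction, and each alternative to them (another normalization, another filter on low counts, another test, a replicate block, and leaving out each replicate), were not run, because 0 of the 20 count columns could be matched to a sample. No paired analysis was possible because the count columns carry no replicate number from the labels. One choice made after the data were examined concerned the look-up of gene names: the 1085 listed names reached 1045 different rows when older symbols and synonyms were accepted, and 1001 when only the listed symbol was.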
